A study of Homo sapiens with 6 samples.

How the data were processed

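RNA sequencing libraries of MCF7 cells infected with MSCV retrovirus, either empty (Vector, n = 3) or carrying a CDYL2 cDNA (labelled CDYL2, n = 3), were compared. Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was taken from sub-confluent cultures with a phenol-based reagent and made into strand-specific total-RNA libraries. The values used were the whole-number read counts per gene that the authors deposited, 1 column per library and 58721 genes in each, without normalization. Per the submitters' processing notes, STAR 2.7.0f, R 3.4.4 and DESeq2 1.14 were used with genome build hg38, with no role given for each. The annotation release, the counting tool and its strand setting are not given in the sources used here, so the counts of overlapping and antisense genes, and of near-identical gene copies, are uncertain.

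Of the 58721 gene identifiers, 58676 matched GENCODE release 29 on GRCh38, which supplied symbols, biotypes and coordinates. The other 45 were copies in the pseudoautosomal region of chromosome Y and held 0 reads. Library totals ran from 28089899 to 53125435 counts. Within each group, pairs of replicates differed by more than sampling noise, so that no library was a duplicate of another. Chi-square per gene lay between 8.32 and 45.1 on average, and a minority of genes carried these averages. The medians, 0.846 to 3.38, also lay above the median that sampling noise alone gives.

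Genes were filtered with filterByExpr at its defaults in edgeR 4.0.16 (R 4.3.3), which left 18262 genes. Counts were scaled by trimmed mean of M values and tested with the quasi-likelihood F test (glmQLFit, glmQLFTest) with the group as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05, with no minimum fold. The common biological coefficient of variation was 8.73%. Levels are CPM with scaled library sizes, principal components used log2 CPM with a prior count of 2, and intervals are at 95%. The floor for a count of 0 was 3 counts per library. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. Intervals of fold changes come from the edgeR fit and include the spread between libraries.

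Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for named genes had been written down. The lists covered epithelial, mesenchymal, luminal, basal and stem markers, NF-kB, IL6/STAT3, interferon and antigen presentation genes, miR-124 targets, chromatin complexes, neuronal genes repressed by REST, cell cycle, p53, hypoxia, unfolded protein, cholesterol, YAP/immediate early and adhesion genes, mitochondrial, ribosomal protein and histone genes, and markers of fibroblasts, leukocytes and endothelium. Some genes belong to several lists. The 23 lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, two-sided, and adjusted over the lists. At this setting 15 lists passed, 11 upward and 4 downward, and with an estimated correlation 1 did, the cholesterol list. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, passed 15 lists. The hypoxia, unfolded protein and histone lists passed camera but not fry, and the miR-124 target, REST and endothelial lists passed fry but not camera. Counts adjusted over the list alone repeat the Benjamini-Hochberg step within each list.

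Named genes were CDYL2, the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change among called genes with a mean of at least 1 CPM and no overlap between groups, up to 4 called members of each list with the smallest adjusted p, and CDH1, VIM, ESR1, CD44, CD24, RELA, NFKB1, STAT3, IL6, EZH2, EHMT2, CDYL and the MIR124 loci whatever their values. SPRY4, LTB, STAT2, TM7SF2, MKI67 and the members of 6 gene lists added later (ductal secretory, fatty acid synthesis, NRF2, lysosome and autophagy, heat shock, nuclear-retained noncoding RNA) were named after their values were seen. A seed test regressed log2 fold changes on the length and GC content of the longest annotated 3′ UTR of each gene and compared genes with and without the 7-base match of miR-124 among 210 shuffles of its letters. Chromosomes were tested as lists with camera, and shares of counts in gene classes with exact two-sided permutation tests.

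Alternatives were DESeq2 1.42.0, limma-voom, relative log expression factors, library size alone, no filter, a stricter filter (1 CPM in 3 libraries), a replicate block, mitochondrial genome genes left out, protein-coding genes only, adjusted p under 0.01, a test against a 1.2-fold change, an estimated correlation between genes, other seed and UTR choices, other denominators for shares, and leaving out each library. The procedure was tested on simulated data with the means and library sizes of these 6 libraries over 18262 genes. Only 200 of these genes were changed, against 9100 called in the data, so the recovery rates do not carry over to the data. For the comparison of libraries labelled CDYL2 with Vector, it recovered 6.12% of genes changed 1.2-fold, 65.3% at 1.5-fold, 83.7% at 2-fold and 100% at 4-fold, and 5 of 126 calls (3.97%) were false. An alternative count column for strand was not run because each library has 1 column.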

Results

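RNA sequencing was used to measure gene expression in MCF7, an established human breast cancer cell line that carries the oestrogen receptor. The 6 libraries fell into 2 groups of 3. The Vector group came from cells infected with an empty MSCV retrovirus, and the other from cells infected with MSCV carrying a CDYL2 cDNA that had been amplified from MCF7 transcripts. Both had been kept in puromycin at 2 µg/mL for 14 days. The deposited gene counts summed to 40639874, 53125435 and 50679771 in Vector replicates 1 to 3, and to 38297320, 28089899 and 33172484 in the libraries labelled CDYL2. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Values are normalised read counts in CPM, scaled to the size of each library, as mean ± SD with n = 3 per group, folds and log2 fold changes compare the libraries labelled CDYL2 with Vector, and coordinates are those of GRCh38 (hg38).

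CDYL2, the introduced gene, encodes a chromodomain protein that binds methylated histone H3. Its locus (ENSG00000166446, chromosome 16, 80597906 to 80804329, minus strand) gave 179.8, 183 and 181 CPM in the Vector libraries. The libraries labelled CDYL2 gave 175.7, 163 and 165.6 CPM. The means were 181 ± 1.68 and 168 ± 6.71 CPM, and the log2 fold change was −0.11 (SE 0.055, 95% interval −0.23 to 0.01; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.123). All 3 libraries labelled CDYL2 thus lay below all 3 Vector libraries, the opposite of what their label says, and the directions given from here on follow the labels alone. Scaling by library size alone gave −0.16 (edgeR adjusted p = 0.0416), and leaving out CDYL2 replicate 1 gave −0.15 (edgeR adjusted p = 0.0183); over all 15 alternatives the adjusted p ran from 0.0183 to 0.311. The gene counts hold reads from the endogenous transcript and from the cDNA together. Its paralogue CDYL stood at 41.4 ± 0.902 and 47.1 ± 2.11 CPM (log2 fold change 0.19, edgeR adjusted p = 0.0215), a call that was lost in 8 of 15 alternatives, where the adjusted p ran from 0.00178 to 0.122.

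The comparison of the groups asks what forced CDYL2 expression does to the transcriptome of these cells, and the series title directs it at MIR124, at NF-kB and STAT3 and at breast cancer cell plasticity. Of 24 tested cholesterol synthesis genes, 22 fell and 1 rose in the libraries labelled CDYL2 (camera adjusted p = 6.03e-26, and adjusted p = 0.0245 with an estimated correlation). FOSB rose 115-fold, from 0.223 ± 0.0542 to 25.4 ± 6.89 CPM, and EGR1, a zinc finger factor induced by growth factors, rose 28-fold, from 2.99 ± 0.366 to 83.1 ± 1.83 CPM. TCN1, which encodes the vitamin B12 carrier haptocorrin, rose 46.3-fold, from 2.64 ± 0.357 to 122.5 ± 3.06 CPM. In the other direction, PRUNE2 fell from 28.9 ± 1.72 to 4.15 ± 0.363 CPM, and NPR3, the clearance receptor for natriuretic peptides, fell from 32.1 ± 1.07 to 5.40 ± 0.886 CPM. The edgeR adjusted p was 2.36e-07 for FOSB, 1.02e-09 for EGR1 and TCN1, 5.24e-08 for PRUNE2 and 2.43e-07 for NPR3.

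Of 18262 genes tested, 9100 (49.8%) passed an adjusted p of 0.05 in edgeR's test, 4687 higher and 4413 lower in the libraries labelled CDYL2. The balance of directions turned with library size alone, at 4088 higher and 5071 lower, but not with relative log expression factors, at 4642 and 4490. DESeq2, which also differs in its test and filter, gave 3991 higher and 4158 lower. A change of at least 2-fold was seen in 1697 of the 9100 genes, 1310 higher and 387 lower. In 10646 genes (58.3%) the 3 values of one group lay wholly above the 3 of the other, against 10% from chance. Among protein-coding genes with a mean of at least 1 CPM and no overlap between groups, the largest increases were in FOSB, CTGF, HMOX1, TCN1, GDF15, KCNE4, ASCL1, HSPA6, ATF3 and EGR1, with log2 fold changes from 6.85 to 4.81. The largest decreases were in NRXN3, RAB7B, PRUNE2, THEG, NPR3, SLC6A19, ROR2, CD36, COL4A6 and GUCY1A2, from −2.99 to −2.27. ASCL1, a neuroendocrine and neuronal bHLH factor, rose from 0.340 ± 0.0896 to 11.7 ± 1.62 CPM. CD36, a fatty acid transporter, fell from 4.06 ± 0.198 to 0.774 ± 0.128 CPM, and ROR2, a WNT5A receptor, from 2.13 ± 0.269 to 0.376 ± 0.237 CPM. HSPA6 shares sequence with other HSP70 genes, so its count is uncertain. KCNE4 had 1, 3 and 5 reads in Vector replicates 1 to 3. It stood at 0.752, 3.31 and 3.34 CPM in CDYL2 replicates 1 to 3, so the size of its rise is uncertain.

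The first principal component of log2 CPM held 73.3% of the variance and separated the groups. The second held 10.3% and set replicate 1 of the libraries labelled CDYL2, at 33.0, apart from replicates 2 and 3, at −19.1 and −7.33. Pearson's r of log2 CPM, computed across genes, lay between 0.989 and 0.996 within groups and between 0.969 and 0.978 across them. Without CDYL2 replicate 1, edgeR called 10300 genes.

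**Figure D1:**
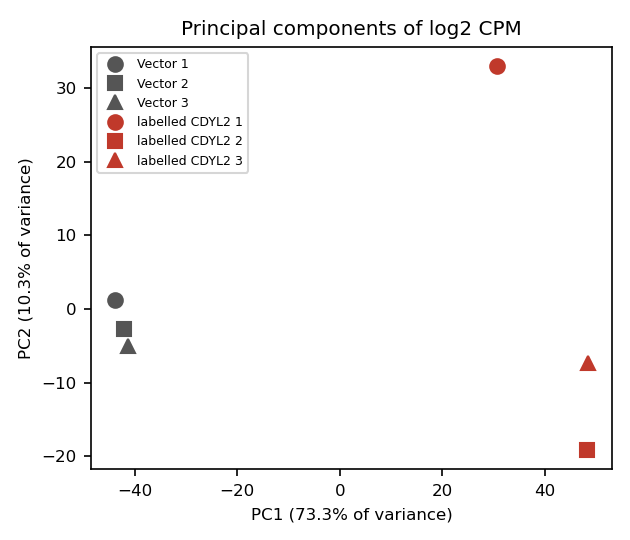
Positions of the 6 libraries on the first (73.3% of variance) and second (10.3%) principal components of log2 CPM, in arbitrary component units, with grey points for Vector, red points for the libraries labelled CDYL2 and one marker shape per replicate number. Vector libraries sit between −43.9 and −41.4 on the first component and the others between 30.6 and 48.5, with CDYL2 replicate 1 alone at 33.0 on the second.

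The list of YAP targets and immediate early genes had the highest median of the 25 lists. Of its 23 tested members, 20 rose and 1, the receptor kinase antagonist SPRY4, fell, with the same counts adjusted over the list alone; the median log2 fold change was 1.90 (camera adjusted p = 7.34e-30, and adjusted p = 0.0823 with an estimated correlation). FOS rose from 9.89 ± 1.39 to 224 ± 18.1 CPM, and DUSP1, a phosphatase that switches off MAP kinases, from 11.9 ± 0.0941 to 70.8 ± 11.3 CPM. CTGF (CCN2), a secreted matrix protein and standard YAP target, rose from 0.0607 ± 0.0166 to 3.78 ± 0.715 CPM, with 2 to 4 reads in each Vector library. The 3 libraries labelled CDYL2 were close to one another for EGR1 (83.2, 81.3 and 84.9 CPM) and TCN1 (119.0, 124.5 and 124 CPM).

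HMOX1, GDF15, ATF3 and DDIT3, which cell stress induces, rose unevenly among the same 3 libraries. HMOX1, the haem-degrading oxygenase, was at 3.80 ± 0.629 CPM in Vector and at 45.0, 247.6 and 251.5 CPM in CDYL2 replicates 1, 2 and 3. GDF15, a stress-induced cytokine of the TGF-beta family, was at 5.13 ± 0.640 CPM in Vector and at 71.7, 255.4 and 260.4 CPM. The stress-induced factors ATF3 and DDIT3 (CHOP) went from 1.85 ± 0.559 to 11.6, 74.3 and 75.8 CPM and from 7.004 ± 2.38 to 16.8, 109.7 and 107.0 CPM. All 4 passed edgeR's test, with adjusted p between 1.66e-05 for GDF15 and 0.000884 for DDIT3.

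**Figure D2:**
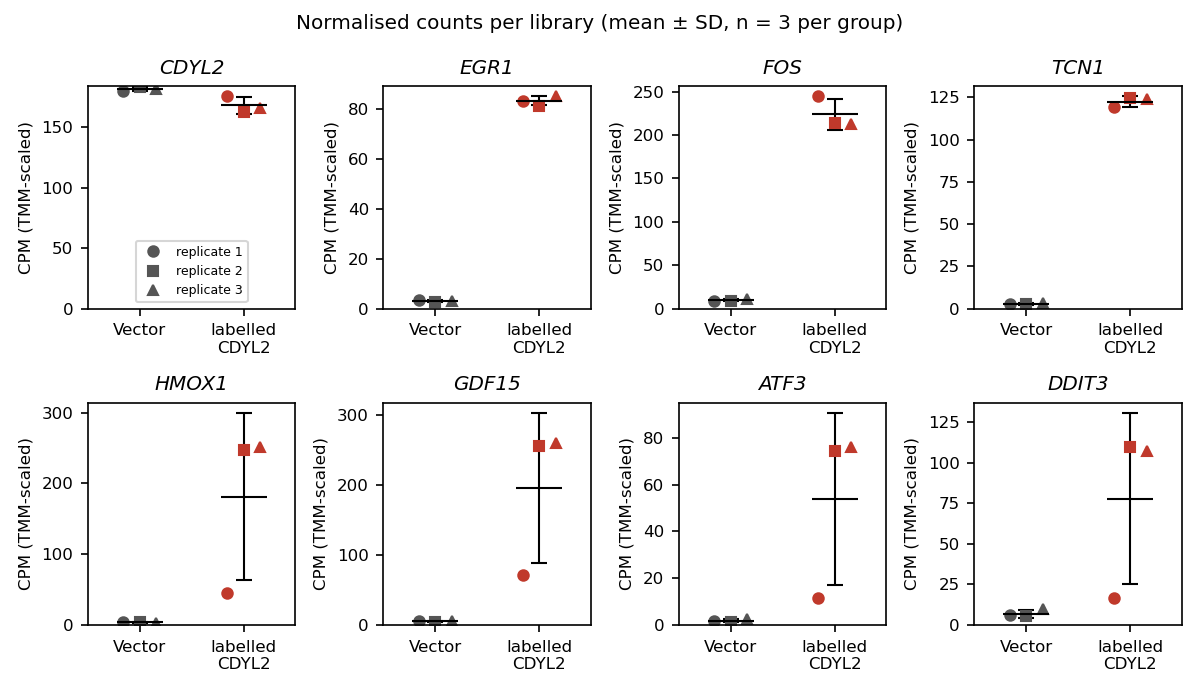
Normalised counts (CPM, linear axes from 0) of CDYL2, EGR1, FOS, TCN1, HMOX1, GDF15, ATF3 and DDIT3 in each library, grouped as Vector (grey) and labelled CDYL2 (red), with one marker shape per replicate number, the group mean as a line and its SD as bars (n = 3). EGR1 is even among the libraries labelled CDYL2 (81.3 to 84.9 CPM), whereas HMOX1 is at 45.0 CPM in replicate 1 and at 247.6 and 251.5 CPM in replicates 2 and 3; CDYL2 itself is not higher in them.

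Unfolded protein and amino acid stress genes had 13 of 25 tested members higher and 1 lower, also when adjusted over the list alone (median 0.67; camera adjusted p = 0.0128, and adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.117). XBP1, a factor of the unfolded protein response, rose from 1416 ± 78.3 to 1907 ± 95.8 CPM, and VLDLR, a lipoprotein receptor, from 6.70 ± 1.33 to 19.1 ± 5.12 CPM. Among p53 targets, 19 of 26 rose and 1 fell, with the same counts adjusted over the list alone (median 0.85; camera adjusted p = 2.84e-05, and adjusted p = 0.608 with an estimated correlation). TP53INP1, a promoter of autophagy and cell death, rose from 20.1 ± 0.691 to 88.1 ± 20.2 CPM and ZMAT3, an RNA-binding p53 target, from 16.1 ± 1.23 to 32.0 ± 1.80 CPM. Hypoxia and glycolysis genes had 17 of 29 higher and 3 lower, again the same adjusted over the list alone (median 0.47; camera adjusted p = 0.0147, and adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.0955). The vasodilator peptide gene ADM rose from 2.44 ± 0.145 to 34.3 ± 12.5 CPM, and NDRG1 from 16.2 ± 3.77 to 86.6 ± 49.3 CPM, with 29.7 CPM in CDYL2 replicate 1 against 113.6 and 116.4 CPM in replicates 2 and 3. Without CDYL2 replicate 1, the higher and lower members numbered 23 and 1 of 26 stress genes, 23 and 1 of the p53 targets, and 20 and 4 of the hypoxia genes. Without Vector replicate 1, 11 hypoxia genes rose.

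NF-kB target and pathway genes, named in the question of the series, had 17 of 26 tested members higher and 1 lower, or 18 and 1 adjusted over the list alone. Their median log2 fold change was 0.55 (camera adjusted p = 0.000521, and adjusted p = 0.618 with an estimated correlation). CXCL8, the neutrophil chemokine, rose from 0.627 ± 0.0656 to 9.47 ± 4.69 CPM, with 4.06 CPM in CDYL2 replicate 1 against 11.9 and 12.4 CPM in replicates 2 and 3. BIRC3, an inhibitor of apoptosis, rose from 13.1 ± 0.867 to 36.9 ± 9.83 CPM. RELA, the p65 subunit of NF-kB, rose from 49.6 ± 2.34 to 72.4 ± 9.40 CPM (log2 fold change 0.54, edgeR adjusted p = 0.000776), whereas NFKB1 stood at 61.1 ± 0.932 and 60.5 ± 5.08 CPM (log2 fold change −0.01, edgeR adjusted p = 0.891). LTB, the member that fell, encodes lymphotoxin beta and had a log2 fold change of −1.02. Leaving out CDYL2 replicate 1 left 19 of 26 higher and 1 lower, with a median of 0.70.

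In the IL6, JAK and STAT3 pathway list, 24 of 33 tested genes rose and 2 fell, the same adjusted over the list alone (median 0.66; camera adjusted p = 1.55e-08, and adjusted p = 0.177 with an estimated correlation). STAT3 rose 1.40-fold, from 65.8 ± 1.22 to 92.1 ± 1.99 CPM (edgeR adjusted p = 6.32e-05), and IL6ST, the shared receptor subunit gp130, 1.60-fold, from 123.7 ± 1.90 to 197 ± 9.31 CPM. IL6 rose 3.13-fold but from very low levels, 0.122 ± 0.0223 to 0.393 ± 0.0415 CPM, which was 5 to 8 reads per Vector library and 12 or 13 per library labelled CDYL2 (edgeR adjusted p = 0.00211). MYC rose from 74.3 ± 8.24 to 190 ± 28.1 CPM.

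The microRNA precursors MIR124-1 and MIR124-2 on chromosome 8, MIR124-3 on chromosome 20 and the host transcript MIR124-2HG had 0 counts in all 6 libraries. A count of 0 allows up to 3 reads per library, or 0.054 to 0.108 CPM, so expression below this was not detectable, and a total RNA library of this kind would not hold the mature microRNA well. LINC00599, the host of MIR124-1, had 1 read, in CDYL2 replicate 3. Among known miR-124 targets, 15 of 35 tested genes rose and 8 fell, or 15 and 9 adjusted over the list alone. Their median log2 fold change was −0.06, their mean 0.05 and camera's direction upward (camera adjusted p = 0.419, fry adjusted p = 0.0116). The glucocorticoid receptor gene NR3C1 rose from 43.2 ± 3.20 to 80.7 ± 0.303 CPM and the cell cycle kinase gene CDK6 from 6.68 ± 0.899 to 14.8 ± 0.793 CPM, while CCNA2 (cyclin A2) fell from 122.8 ± 4.93 to 64.5 ± 10.9 CPM. For 13290 protein-coding genes with an annotated 3′ UTR, the mean residual log2 fold change of the 2210 genes with a miR-124 seed match (GTGCCTT), minus that of the others, was −0.0012. The 210 shuffles of the same letters gave a 95% range of −0.06 to 0.06 (two-sided permutation p over the shuffled motifs 0.914), and genes are not independent replicates. With no MIR124 transcript detected in Vector, there may have been little miR-124 activity to lose. The seed test therefore does not decide whether such activity fell.

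**Figure D3:**
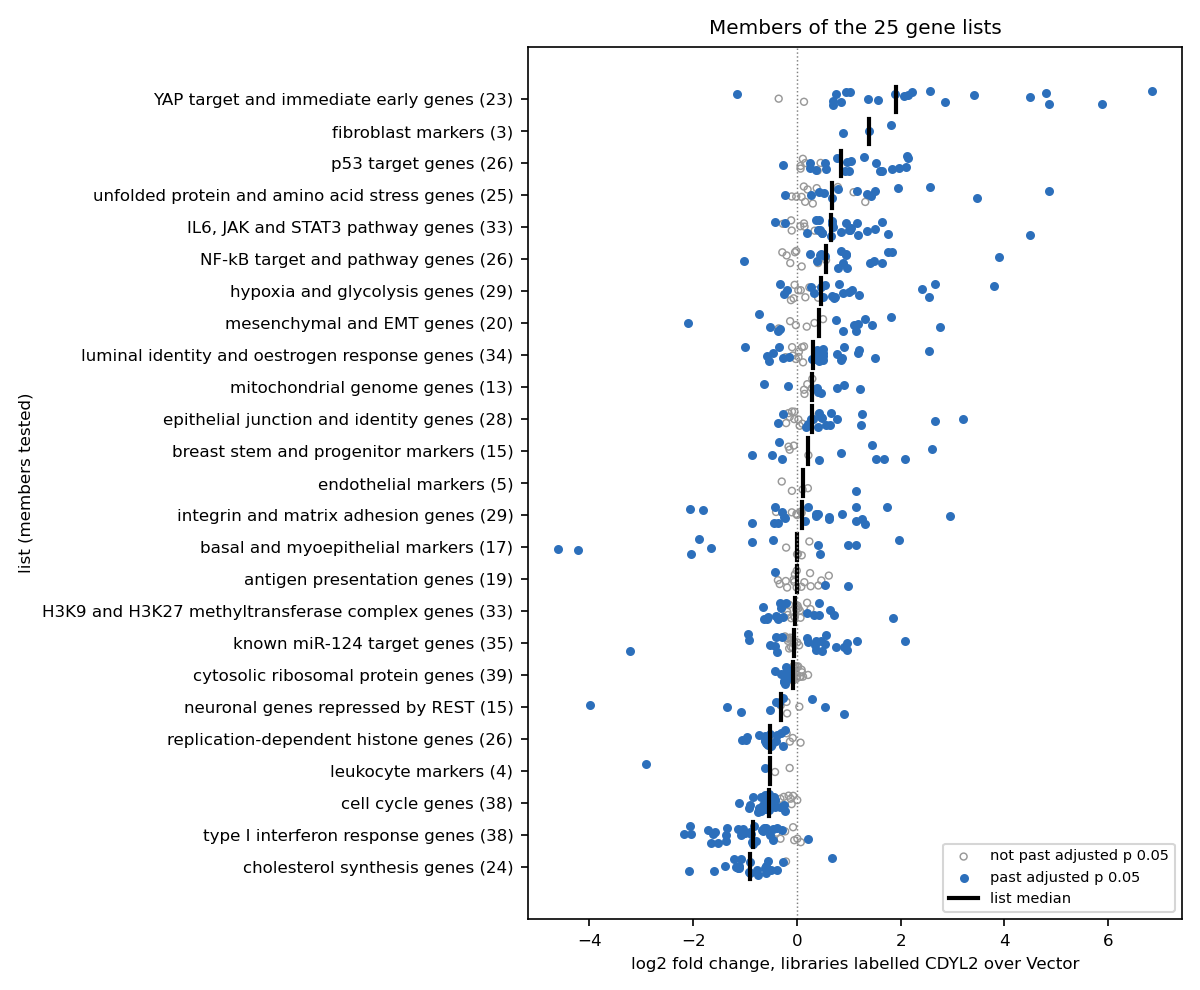
The log2 fold change (libraries labelled CDYL2 over Vector, n = 3 per group) of each tested member of the 25 gene lists, with filled points for genes past an adjusted p of 0.05 in edgeR's test, open points for the others and a bar at the list median; the number tested is in brackets. YAP target and immediate early genes have the highest median, 1.90, and cholesterol synthesis genes the lowest, −0.90.

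The epithelial and the mesenchymal list both moved upward in camera's test. In the epithelial junction and identity list, 16 of 28 genes rose and 2 fell, or 16 and 3 adjusted over the list alone (median 0.30; camera adjusted p = 0.000279, and adjusted p = 0.148 with an estimated correlation); without CDYL2 replicate 1, 4 fell. The epithelial factor gene ELF3 rose from 12.4 ± 0.640 to 114.7 ± 28 CPM, the mucin gene MUC1 from 8.88 ± 2.51 to 55.6 ± 2.60 CPM and the tight junction gene CLDN4 from 89.1 ± 3.88 to 209 ± 28.3 CPM. CDH1, which encodes E-cadherin, stood at 1094 ± 14.7 and 1134 ± 56.8 CPM (log2 fold change 0.05, edgeR adjusted p = 0.481). Of the mesenchymal list, 9 of 20 tested genes rose and 5 fell, the same adjusted over the list alone (median 0.42; camera adjusted p = 0.0128, and adjusted p = 0.214 with an estimated correlation); limma-voom gave an adjusted p of 0.0988, in a range of 0.00329 to 0.214 over 16 alternatives. The collagen gene COL1A1 rose from 6.87 ± 0.479 to 24.3 ± 2.15 CPM and the matrix gene TGFBI from 2.66 ± 0.335 to 18.2 ± 6.16 CPM. VIM, the vimentin gene, was low in both groups, at 2.45 ± 0.143 and 2.23 ± 0.0927 CPM (log2 fold change −0.13, edgeR adjusted p = 0.437).

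Luminal identity and oestrogen response genes had 18 of 34 members higher and 7 lower, or 18 and 8 adjusted over the list alone (median 0.30; camera adjusted p = 0.000988, and adjusted p = 0.203 with an estimated correlation). STC2, a secreted glycoprotein gene induced by oestrogen, rose from 133.7 ± 10.3 to 782 ± 174 CPM and CTSD (cathepsin D) from 245.6 ± 11.9 to 562.5 ± 21.5 CPM. ESR1, the oestrogen receptor alpha gene, stood at 312.7 ± 13 and 321 ± 38.9 CPM (log2 fold change 0.04, edgeR adjusted p = 0.739). Of 17 basal and myoepithelial markers, 5 rose and 7 fell, or 6 and 7 adjusted over the list alone, with a median of 0.00, a mean of −0.63 and camera's direction downward (camera adjusted p = 0.392). TP63, the basal transcription factor gene, fell from 16.9 ± 1.63 to 4.59 ± 0.416 CPM, KRT17 fell from 6.73 ± 0.453 to 1.64 ± 0.110 CPM, and KRT15 rose from 5.06 ± 0.519 to 19.9 ± 2.50 CPM; keratin genes share sequence with close copies, so their counts are uncertain. Stem and progenitor markers had 7 of 15 higher and 4 lower, the same adjusted over the list alone (median 0.22; camera adjusted p = 0.0125, and adjusted p = 0.177 with an estimated correlation), and limma-voom gave an adjusted p of 0.182. The median was 0.13 without Vector replicate 3 and 0.09 with the stricter low-count filter. KLF4 rose from 28.3 ± 1.37 to 90.2 ± 12.8 CPM, SOX2 from 0.897 ± 0.148 to 5.37 ± 0.764 CPM and NOTCH1 from 15.9 ± 0.749 to 43.5 ± 3.22 CPM. Of the surface markers used to sort breast cancer stem cells, CD44 fell from 14.0 ± 0.944 to 10.95 ± 0.318 CPM (edgeR adjusted p = 0.00439) and CD24 rose from 295.7 ± 10.7 to 394.7 ± 16 CPM (edgeR adjusted p = 0.000282). Such sorting selects high CD44 and low CD24, so both changes run against it. Both genes belong to the stem list, where the rise of CD24 counts among the 7 higher members.

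Type I interferon response genes were lower nearly throughout. Of 38 genes, 30 fell and 1 rose, the interferon signal transducer STAT2; adjusted over the list alone 31 fell and 1 rose (median −0.84; camera adjusted p = 1.46e-21, and adjusted p = 0.148 with an estimated correlation). IFIT1, which binds viral RNA, fell from 55.0 ± 6.31 to 12.1 ± 1.99 CPM, MX1, an antiviral GTPase gene, from 72.5 ± 5.10 to 25.2 ± 2.89 CPM, and OAS2, a sensor of double-stranded RNA, from 60.7 ± 5.80 to 19.2 ± 1.89 CPM. Antigen presentation genes moved less, with 2 of 19 higher and 1 lower, or 2 and 0 adjusted over the list alone; 4 of 20 were higher and 1 lower without Vector replicate 2, and 3 of 19 higher and 0 lower without Vector replicate 3. Their median was −0.0034, their mean 0.11 and camera's direction upward (camera adjusted p = 0.616). HLA-E rose from 32.6 ± 4.39 to 47.3 ± 2.95 CPM, while the call of CIITA, at 2.71 ± 0.384 and 2.02 ± 0.148 CPM (edgeR adjusted p = 0.0412), was lost in 6 of 15 alternatives, where the adjusted p ran from 0.0218 to 0.133. Reads of HLA genes can be split among near-identical copies, so these counts are uncertain.

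The H3K9 and H3K27 methyltransferase complex list, which holds the enzymes that CDY family proteins are known to bind, had 7 of 33 genes higher and 11 lower, or 8 and 11 adjusted over the list alone (median −0.04; camera adjusted p = 0.534). The list also holds demethylases of these marks, with KDM6B and KDM4B among the higher members, and CDYL and CDYL2 themselves. Its counts, median and p therefore mix opposing enzymes. Without CDYL2 replicate 1, 14 were lower and the median was −0.10, and without CDYL2 replicate 2 it was −0.01. KDM6B, an H3K27 demethylase gene, rose from 9.52 ± 0.724 to 34.6 ± 8.63 CPM, and CBX3, which encodes heterochromatin protein 1 gamma, fell from 305.8 ± 3.47 to 204 ± 13.5 CPM. EZH2 stood at 52.8 ± 2.76 and 46.4 ± 4.51 CPM (log2 fold change −0.19, edgeR adjusted p = 0.0682), and passed the threshold in 4 of 15 alternatives, where its adjusted p ran from 0.0199 to 0.199. EHMT2, the gene of the H3K9 methyltransferase G9a, stood at 40.1 ± 2.45 and 38.8 ± 3.72 CPM (log2 fold change −0.04, edgeR adjusted p = 0.665). Of neuronal genes repressed by REST, 3 of 15 rose and 7 fell, the same adjusted over the list alone (median −0.31; camera adjusted p = 0.236, fry adjusted p = 0.00485). The adhesion gene L1CAM rose from 15.6 ± 2.58 to 29.2 ± 2.07 CPM and the synaptic gene UNC13A fell from 9.17 ± 0.579 to 4.33 ± 0.441 CPM. CHGA had 12 to 22 reads in each Vector library and 0 or 1 in those labelled CDYL2.

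Cell cycle genes were lower together. Of 38 genes 31 fell and the other 7 did not pass edgeR's test, and 32 fell adjusted over the list alone (median −0.54; camera adjusted p = 9.55e-09, and adjusted p = 0.599 with an estimated correlation). MCM7, a subunit of the replicative helicase, fell from 322 ± 4.54 to 173 ± 35.5 CPM and PCNA, the DNA polymerase clamp, from 185.5 ± 10.2 to 110.6 ± 17.9 CPM. MCM7 was at 213.9 CPM in CDYL2 replicate 1 and at 150.6 and 154.5 CPM in replicates 2 and 3, and without replicate 1, 36 genes of the list fell. The proliferation marker gene MKI67, looked up after the values were seen, stood at 328 and 329 CPM (log2 fold change 0.01, edgeR adjusted p = 0.981). Replication-dependent histone genes had 21 of 26 lower in edgeR's test, also when adjusted over the list alone (median −0.51; camera adjusted p = 3.41e-05, and adjusted p = 0.618 with an estimated correlation; fry adjusted p = 0.0504). HIST1H4H fell from 142 ± 12.7 to 101 ± 6.19 CPM and HIST1H2BO from 93.1 ± 13.4 to 47.9 ± 8.82 CPM, although near-identical copies make histone counts uncertain.

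Cholesterol synthesis genes fell nearly throughout. Of 24 tested genes 22 fell and 1 rose, the sterol reductase gene TM7SF2, or 23 and 1 adjusted over the list alone (median −0.90; camera adjusted p = 6.03e-26, and adjusted p = 0.0245 with an estimated correlation). It was the only one of 15 lists past camera's test to hold with an estimated correlation. STARD4, a cytosolic sterol carrier gene, fell from 30.6 ± 2.19 to 7.30 ± 0.693 CPM, and INSIG1, the sterol-sensing retention factor of the endoplasmic reticulum, from 113 ± 5.88 to 37.2 ± 3.01 CPM. The synthesis enzyme genes DHCR7 and IDI1 fell from 269.9 ± 1.54 to 124 ± 1.17 CPM and from 149.6 ± 5.67 to 67.8 ± 1.78 CPM.

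Integrin and matrix adhesion genes moved both ways, with 14 of 29 higher and 9 lower, or 14 and 10 adjusted over the list alone (median 0.09; camera adjusted p = 0.0206, and adjusted p = 0.595 with an estimated correlation). That call was also lost with limma-voom (adjusted p = 0.18) and without Vector replicate 1 (camera adjusted p = 0.0563), and the p ran from 0.000514 to 0.595 over 16 alternatives. Scaling by library size alone gave a median of 0.04. COL12A1, a fibril-associated collagen gene, rose from 16.4 ± 2.03 to 127 ± 9.11 CPM, and ITGB6, an epithelial integrin subunit, fell from 19.7 ± 1.86 to 5.61 ± 0.277 CPM. Of 13 genes of the mitochondrial genome, 6 rose and 2 fell, or 7 and 2 adjusted over the list alone (median 0.30; camera adjusted p = 0.0806, past the threshold in 6 alternatives, among them without Vector replicate 2, at 0.0344, or CDYL2 replicate 3, at 0.0135). MT-ND5 rose from 298 ± 46.4 to 693.5 ± 77.8 CPM. Among 39 cytosolic ribosomal protein genes, 10 fell and the other 29 did not pass edgeR's test, and 5 fell adjusted over the list alone (median −0.07; camera adjusted p = 0.102, past the threshold in 4 alternatives). Without Vector replicate 2 that p was 0.0078 by camera, the median was −0.15 and 16 fell, while 4, 5 and 5 fell without Vector replicate 1, Vector replicate 3 (median −0.04) or CDYL2 replicate 3. RPL35 fell from 509 ± 60.4 to 382 ± 16.1 CPM.

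Markers of other cell types were scarce. Only 3 of 12 fibroblast markers had enough reads to be tested, and all 3 rose, among them PCOLCE from 1.02 ± 0.0778 to 2.66 ± 0.236 CPM; COL1A1 and COL3A1 are also in the mesenchymal list. Of 4 tested leukocyte markers 2 fell, CSF1R from 1.02 ± 0.0900 to 0.135 ± 0.0440 CPM and ITGAM from 2.95 ± 0.350 to 1.95 ± 0.378 CPM, and of 5 endothelial markers ENG alone rose, from 1.64 ± 0.182 to 3.59 ± 0.257 CPM. These counts were the same adjusted over the list alone. The ITGAM call was lost without Vector replicate 3 (edgeR adjusted p = 0.061, against 0.00118 to 0.061 over 15 alternatives), and camera gave the endothelial list an adjusted p of 0.535 (fry adjusted p = 0.0281).

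As shares of all gene counts, long intergenic noncoding RNAs took 0.976 ± 0.0807% in Vector and 1.82 ± 0.231% in the libraries labelled CDYL2. Single abundant long noncoding RNAs can carry such a share, and MALAT1 stood at 6385 and 13450 CPM and NEAT1 at 388.5 and 1751 CPM. Of 1065 tested long intergenic noncoding genes, 263 rose and 111 fell, with a median log2 fold change of 0.138. Mitochondrial ribosomal RNA took 24.3 ± 1.25% and 26.7 ± 0.0929%, mitochondrial mRNA 1.47 ± 0.0937% and 1.71 ± 0.145%, and the 10 most abundant genes 29.4 ± 1.57% and 32.2 ± 0.564%. Histone mRNA took 0.418 ± 0.0476% and 0.298 ± 0.0327%, ribosomal protein mRNA 2.29 ± 0.113% and 2.07 ± 0.0424%, protein-coding genes in all 71.7 ± 1.60% and 68.4 ± 0.736%, and sense-intronic genes 0.0569 ± 0.00377% and 0.0614 ± 0.000547%. Each of these 8 shares separated the groups completely, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow (adjusted 0.112 over 9 shares). Some classes hold the same genes and all are parts of 1 total, so the 8 shares are not independent. Over protein-coding counts alone the ribosomal protein share overlapped, at 3.20 ± 0.227% and 3.02 ± 0.0538% (exact permutation p = 0.4). The share of miscellaneous small RNA genes, 1.76 ± 0.481% and 1.68 ± 0.802%, overlapped between the groups. Of 24 chromosomes tested as lists, 0 passed camera's adjusted threshold, with 2 at an unadjusted p under 0.05 (chromosomes 17 and 21); with an estimated correlation chromosome 17 passed (median log2 fold change 0.12, camera adjusted p = 0.0358).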

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

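Every alternative was planned. DESeq2 called 8149 genes, limma-voom 9018, relative log expression factors 9132, library size alone 9159, no filter 9773, the stricter filter 8139, no mitochondrial genome genes 9149, protein-coding genes only 7795 and an adjusted p under 0.01 6404, against 9100; DESeq2 called 7904 and limma-voom 8939 of those 9100. The test against a 1.2-fold change called 5106, since it asks for a larger change, and the stricter filter left 1030 genes changed at least 2-fold in place of 1697, since it tests fewer low genes. Leaving out 1 library gave 7402 to 10300 calls. Whether the replicate numbers pair the libraries stays open. Deviations of same-numbered libraries correlated weakly, at 0.0825, 0.135 and 0.126, but each correlated best with its own number. Libraries with different numbers correlated at −0.166 to 0.0478. The replicate block called 9306 genes, and brought EZH2 (log2 fold change −0.19, edgeR adjusted p = 0.0381) and the mitochondrial genome list (camera adjusted p = 0.00173) past the threshold. Of 1732 values of the 116 tested named genes other than CDYL2, 1707 kept their direction and side of the threshold, 15 lost the call, 4 gained it (all of EZH2) and 6 changed sign. Of 270 values of 17 lists, all but the epithelial, mesenchymal, stem, NF-kB, STAT3 and miR-124 lists, the numbers were 230, 11, 10 and 19. CDYL2 passed as lower with library size alone (−0.161) and without CDYL2 replicate 1 (−0.148), kept its side of the threshold in the other 13 alternatives, and ran from −0.148 to −0.0888 with 1 library left out. Uncalled genes near 0 changed sign: ESR1 (−0.0144 with library size alone, −0.0699 to 0.101 with 1 library left out), NFKB1 (0.0058 with protein-coding genes only, −0.0599 to 0.0508 with 1 library left out) and EHMT2 (−0.131 to 0.0048 with 1 library left out). With an estimated correlation 1 list and 1 chromosome passed, and the epithelial (median 0.296), mesenchymal (0.42), stem (0.221), NF-kB (0.553) and STAT3 (0.656) lists did not, with medians as before; limma-voom lost the mesenchymal (0.421) and stem (0.224) lists. The basal median turned negative with DESeq2 (−0.0181), relative log expression (−0.0037), library size alone (−0.0481), no filter (−0.0236) and no mitochondrial genes (−0.0060), and ran from −0.107 to 0.0255 with 1 library left out. The antigen presentation median turned positive with DESeq2 (0.0199), no filter (0.0149), the stricter filter (0.0066), no mitochondrial genes (0.0322) and protein-coding genes only (0.0148), and ran from 0.0104 to 0.121 with 1 library left out, against −0.0539 to 0.121 over all 16 alternatives. The miR-124 target median ran from −0.091 to 0.0022 with 1 library left out and from −0.108, with library size alone, to 0.0022 over all 16 alternatives, above 0 only without CDYL2 replicate 1, and the seed difference was 0.0058 with 8-base sites, 0.0058 with the first transcript's UTR and −0.0069 to 0.00056 with 1 library left out. For these changes of sign the cause was not tested; all lie close to 0. With 200 of 18262 simulated genes changed, 6.12% of 1.2-fold changes were recovered at this depth and 3 libraries per group. The adjusted threshold is stricter when few genes change, so this rate does not carry over to data with 9100 calls. What limited the recovery was not tested. IL6 and the MIR124 loci lie near the floor.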

Other observations

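The gene lists, neighbour correlation and windows in this and the next 2 paragraphs, the tests on CDYL2 and the tests of nuclear RNA were chosen only after the results were seen. A list of 14 tested ductal secretory and luminal progenitor genes, some of them shared with other lists, had 12 higher and 1 lower in the libraries labelled CDYL2, also when adjusted over the list alone. No test is given of this list or of the 5 that follow, since they were put together from values already seen and several hold genes already named for their rises (TCN1, ELF3 and ASCL1 here). ASCL1, described above as a neuroendocrine and neuronal factor, is counted in this list although the list's name does not cover it. LCN2, the iron-binding lipocalin, rose from 4.09 ± 0.392 to 62.1 ± 1.13 CPM, the calcium-binding S100P from 15.5 ± 0.843 to 111 ± 17.6 CPM and the receptor kinase gene ERBB4 from 3.68 ± 0.493 to 30.3 ± 2.66 CPM (SD, n = 3), while S100A8, a neutrophil and epithelial alarmin gene, fell from 36.8 ± 7.19 to 19.7 ± 1.27 CPM. Of 15 fatty acid synthesis genes, 11 were lower and 3 higher, the same adjusted over the list alone. SCD, the stearoyl-CoA desaturase, fell from 1644 ± 42.9 to 400.6 ± 13.3 CPM and ACLY, which makes cytosolic acetyl-CoA, from 225 ± 4.23 to 141.6 ± 12.2 CPM, whereas FASN, the fatty acid synthase, rose from 214.9 ± 16.3 to 302 ± 36.7 CPM.

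NRF2 targets of the oxidative stress response had 14 of 19 genes higher and 1 lower, or 15 and 1 adjusted over the list alone, with HMOX1 among them. The quinone reductase gene NQO1 rose from 475.5 ± 14.0 to 1084 ± 41.5 CPM and G6PD, the entry enzyme of the pentose phosphate pathway, from 168.9 ± 4.83 to 391.6 ± 8.24 CPM. Lysosome and autophagy genes had 12 of 21 higher and 1 lower, the same adjusted over the list alone. CTSD, already named for its rise, is a member, as is GABARAPL1, an autophagosome protein gene, at 0.508 ± 0.0205 and 7.21 ± 2.79 CPM. Of 14 heat shock genes, 6 rose, HSPA6 among them, and 3 fell, or 8 and 4 adjusted over the list alone; HSP90AB1 fell from 2681 ± 37.9 to 1879 ± 69.4 CPM. The list of nuclear-retained long noncoding RNAs had 6 of 10 higher and 1 lower, the same adjusted over the list alone. NORAD, 1 of the 6, is mostly cytoplasmic, so the list's name does not cover it. NEAT1, the scaffold of paraspeckles, rose from 388.5 ± 44.7 to 1751 ± 164 CPM and MALAT1 from 6385 ± 556 to 13450 ± 1990 CPM.

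Neighbouring genes moved together, with a Spearman correlation across genes of 0.137 between a gene's log2 fold change and the median of its 50 nearest tested neighbours, against at most 0.0179 in 100 shuffled gene orders; genes are not independent replicates. At the end of chromosome 22 (49933198 to 50801309), 18 of 31 tested genes were higher and 2 lower, with a median of 0.65, and 0.41 after removal of a trend on GC content and length (mean GC 62.3% against 49.8% over all tested genes). At the start of chromosome 9 (14521 to 5339873), 17 of 37 were higher and 5 lower, with a median of 0.47, and 0.48 after that removal. It holds 8 mitochondrial pseudogenes, which can take reads of mitochondrial genome genes; without them 11 of 29 were higher and 5 lower, with a median of 0.16. On chromosome 6 (26021679 to 27256624), a window that holds a histone gene cluster had 28 of 51 genes lower and 7 higher, with a median of −0.49.

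CDYL2 reads were not higher in the libraries labelled CDYL2, although the labels report that expression had been checked at the protein level. Scaling between libraries stays open: the highest log2 fold change under 5 other scalings was −0.0917, but these differ too little to decide it. An exchange of all labels stays open: the interval of the log2 fold change, with a lower end of −0.233, excludes a change of 0.58 in either direction, and so does not separate exchanged labels from correct ones. A few transduced copies beside a long endogenous transcript stay open: the coding sequence spans 1521 of 8557 exonic bases, and even coverage with an unchanged endogenous level would leave room for at most 4.88 added copies per 100 endogenous transcripts, but neither assumption could be checked from gene counts. Low expression of the cDNA, or a fall of the endogenous transcript that offset it, may therefore be present and cannot be told apart here.

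Immediate early genes were higher together with MALAT1 and NEAT1. The median log2 fold change of 388 sense-intronic genes was 0.223, with a bootstrap interval of 0.143 to 0.277. The bootstrap resampled genes, which are not independent replicates, so the interval leaves out the spread between libraries. The interval's upper end lay below 1.24, so the sense-intronic genes rose less than the immediate early list. That bound, the immediate early median of 1.90 minus the SD of the sense-intronic genes, was set after the values were seen. It also takes for granted that both sets of genes follow nuclear RNA alike, which was not tested. The interval's lower end lay above 0, but an interval over genes does not measure a difference between the groups. A larger share of nuclear RNA therefore stays open, as the whole cause or as part of it. A single aberrant library was argued against, since the lowest median of the immediate early list without 1 of the libraries labelled CDYL2 was 1.77. A difference in handling, serum or density at harvest, or an effect of CDYL2, may raise the same genes; these were not tested, because they are confounded and the labels do not describe the harvest of each library.

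Close to 50% of tested genes passed the threshold, and the 9100 calls were not explained by the trends that could be removed. Removal of a smooth trend on GC content and exonic length left 9294 calls, and subtraction of the running median of the 50 nearest genes, as long blocks of copy number would require, left 9029. That running median had an SD of 0.123 and does not follow blocks much shorter than 50 genes. Shorter changes in copy number therefore stay open. The real grouping was 1 of 10 splits of the 6 libraries with as many calls, the highest of the others having 0. In edgeR's test the others had 72 to 595 genes at an unadjusted p under 0.05, against 10230. Each other split mixes the groups, so the group difference adds to the spread within it and few calls were fixed in advance. These splits therefore give no reference for chance, and 10 are too few for a share under 0.05. Divergence of the separately selected cell pools, a difference in culture or library preparation, and a response to CDYL2 may each produce so many calls, and none of these was tested.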
